A study of Homo sapiens with 4 samples.

How the data were processed

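Total RNA was profiled on 4 single-colour bead arrays of MDA-MB435 cells, 2 of cells given an empty lentiviral vector and 2 of cells given a vector encoding SEMA3B. Per the labels' protocols, 500 ng of total RNA per sample was reverse transcribed, amplified with T7 RNA polymerase and labelled with biotin. The submitters' processing notes name BeadStudio, the scanner maker's software, and no version or normalization is given in the sources used here. Per the file headers, each deposited per-array file holds, for each target, the average bead intensity, a bead spread, the number of beads and a detection score.

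The deposited intensity values of the 4 arrays had not been brought to a common scale: their medians were 97.3, 88.1, 86.8 and 90.2 and their maxima ranged from 16358 to 21128. The deposited detection score ran from about 0 for dim targets to 1 for bright ones, so 1 minus the score was used as a detection p. The deposited bead spread fell with the number of beads (slopes of log spread on log beads of -0.42 to -0.53 among the dimmer targets), as a standard error does and a standard deviation does not, and it was used as a standard error. The second deposited table, the authors' processed values, also holds intensity. Matched in sorted order, its 4 columns were the per-array values minus a background of 93.0, 83.7, 83.1 and 86.9, divided by 1, 1.45, 1.11 and 1.13 for the 2 empty vector and the 2 SEMA3B arrays in order, with residuals of at most 0.0946. The authors' processed values were therefore on a linear scale, background-subtracted and scaled to the first empty vector array, with no centring of targets. Their column medians were 4.3, 3.0, 3.3 and 2.9. Of its 47289 rows, 47147 were matched to 1 target on all 4 arrays within 0.2 intensity units, including all 6702 tested targets. How the authors chose the scaling factors is not given in the sources used here.

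The average bead intensities were background-corrected and quantile-normalized with neqc in limma 3.58.1 under R 4.3.3. It takes the level of the negative controls from the detection p, adds an offset of 16 and gives log2 values. Targets with a detection p below 0.01 on at least 2 of the 4 arrays, whatever their group, were tested. The test was limma's linear model with moderated variances and an intensity trend, 2 arrays per group, two-sided, with Benjamini-Hochberg adjustment over all tested targets and a threshold of 0.05. Each SE given for a log2 difference is the moderated one of that model. The number of arrays limits the precision: an exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so no such test was used for single targets. The same fit was tested on simulated data for this comparison, with the spread estimated from the 4 arrays and 200 of 6702 targets changed. It recovered 3.8% of 1.5-fold, 25.6% of 2-fold, 80.3% of 3-fold and 94.9% of 4-fold changes over 20 simulations, and 4.17% of its calls were false.

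The groups and replicate numbers were taken from the sample titles. The design text of the series calls the arrays of a group biological duplicates. The replicate numbers are not tied to a shared animal, day or batch in the labels. Slide and scan date are not given in the sources used here.

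The design, the alternatives, 31 gene lists and the rule for naming genes were fixed before the data were examined. That rule took SEMA3B and the interleukin-8 gene, then the largest changes past the threshold, then members of each list. The files identify targets by sequence record numbers and do not pair them with gene symbols, and 0 of the 47289 identifiers matched the reference gene table used here. SEMA3B, the interleukin-8 gene and the 31 gene lists were therefore not analysed here, and neither were the list tests with limma's camera or their alternatives. In place of named genes, the 2 targets with the smallest unadjusted p in each direction are given by their identifiers, among those whose 2 SEMA3B arrays lay on one side of both empty vector arrays. This adaptation of the rule was made after the data were seen. For a target not detected on either array of a group, the fold is a bound. It was computed against the lowest normalized level of a detected target on each array or the target's own level, whichever was higher.

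The alternatives were no background correction, normexp with an offset of 50, median scaling in place of quantile normalization, the authors' processed values, no filter on dim targets, detection on all 4 arrays, no intensity trend, the replicate number as a block, a threshold of at least 2-fold, and leaving out each array in turn. Array weights from limma were added after the data were seen.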

Results

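The series asked which transcripts change when SEMA3B, a secreted semaphorin first known from axon guidance, is expressed in MDA-MB435 tumour cells from a lentiviral vector. MDA-MB435 is an established human line that was long used as a breast cancer model and was later matched by genotyping to a melanoma line. There were 4 arrays, 2 of empty vector cells and 2 of SEMA3B cells. Each array reported 47289 targets with a median of 35 to 39 beads per target. At a detection p below 0.01, 6439 and 6913 targets were detected on the 2 empty vector arrays, and 6557 and 5818 on the 2 SEMA3B arrays. The targets fall into 3 classes by the prefix of their identifier. Of the 26091 targets named by a GenBank sequence number (prefix GI), 24.7% were detected on at least 2 arrays. The share was 1.26% of the 11622 targets named by a UniGene cluster (prefix Hs) and 1.22% of the 9576 targets with the prefix hmm. The 6702 targets tested were thus 96.1% GI targets, and 5491 targets were detected on all 4 arrays.

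The targets are not paired with gene symbols in the files, so the level of SEMA3B itself, which would check the labels, is not given here. The same holds for the gene of interleukin-8, the neutrophil-attracting chemokine that the title of the series names.

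The arrays of one group were no closer to each other than to arrays of the other group. Over the 6702 tested targets the 2 empty vector arrays correlated at r = 0.961 (Spearman 0.940) and the 2 SEMA3B arrays at r = 0.949 (Spearman 0.924). The 4 pairs from different groups had r from 0.957 to 0.974 (Spearman 0.937 to 0.959), and the closest pair of all was empty vector replicate 2 with SEMA3B replicate 1. These are correlations across targets, which are not independent replicates. The mean r was 0.955 within groups and 0.965 between groups. The difference was -0.01 and turned to 3.2e-04 when SEMA3B replicate 1 was left out. The SD of the log2 differences was 0.403 between the empty vector arrays and 0.463 between the SEMA3B arrays, the widest of the 6 pairs.

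**Figure D1:**
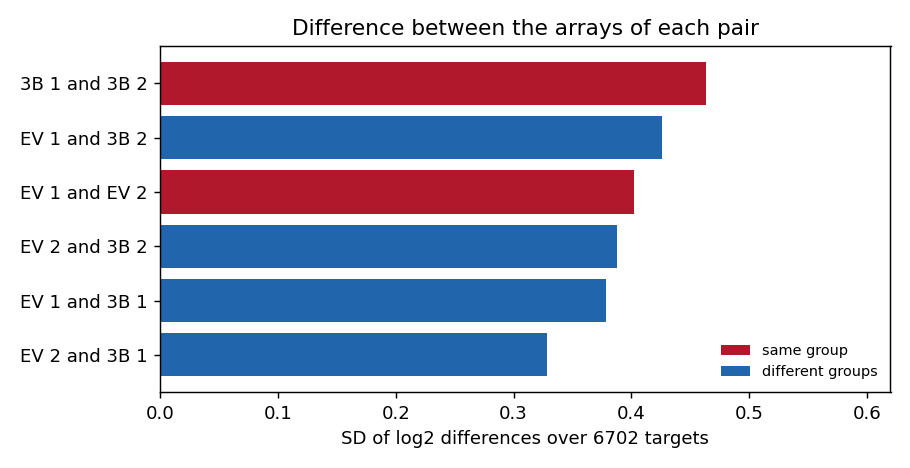
Bars give the SD, over 6702 tested targets, of the log2 intensity difference between the 2 arrays of each pair (EV, empty vector; 3B, SEMA3B; the number is the replicate), in red for arrays of one group and in blue for arrays of different groups. The 2 SEMA3B arrays differed most (0.463) and empty vector replicate 2 and SEMA3B replicate 1 differed least (0.328).

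The 4 arrays can be parted into 2 pairs in 3 ways, each of which would hold 33.3% of the variation between arrays if all arrays varied alike with no effect. The labelled groups held 21.5% of it (bootstrap SD over targets 0.439). The split by replicate number held 38.8% (SD 0.696) and the remaining split 39.7% (SD 0.627). These SDs come from resampling targets on the same 4 arrays. They do not measure how far the shares would stray from 33.3% with other arrays. The 2 SEMA3B arrays lay on one side of both empty vector arrays for 1569 targets, or 23.4% of those tested, where chance gives 33.3%. The other splits separated 34.7% and 41.6%. With the tested targets parted by mean intensity into 4 bins of 1675 or 1676, the group share was 22.5%, 21.2%, 19.7% and 22.6% from the dimmest bin to the brightest.

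Between SEMA3B and empty vector cells, no target passed the test. With limma, 0 of 6702 targets had an adjusted p below 0.05, and the smallest adjusted p was 0.316. At an unadjusted p below 0.05 there were 81 targets, 45 higher and 36 lower in SEMA3B cells, where 335.1 would be expected with no effect if p-values were uniform. The balance of directions differed between ways to obtain the values: 61 targets were higher and 31 lower with median scaling, which kept more higher than lower, and 28 were higher and 51 lower with the authors' processed values, which differ in both background correction and scaling. The number changed with each array that was left out. It was 51 without empty vector replicate 1, 165 without empty vector replicate 2, 401 without SEMA3B replicate 1 and 196 without SEMA3B replicate 2. Without SEMA3B replicate 1, 4 targets passed the adjusted threshold, all lower in the remaining SEMA3B array. The central 90% of targets had log2 differences between -0.38 and 0.36, with a median SE of 0.27. A difference of at least 1.5-fold was seen for 108 targets, 44 higher and 64 lower, against 373 in the split by replicate number and 388 in the remaining split. In simulated data with this spread the test recovered 25.6% of 2-fold and 80.3% of 3-fold changes. Most changes of about 2-fold or less were thus missed even there. The simulation changed more targets than the 5 that differed by over 2-fold between these groups. Data with fewer changed targets were not simulated, so the rates may be too high for these arrays. The simulated noise was also independent and alike on all arrays, which gives each split about 33.3% of the variation without an effect. The labelled groups here held 21.5%. How the rates would change with such arrays was not tested.

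**Figure D2:**
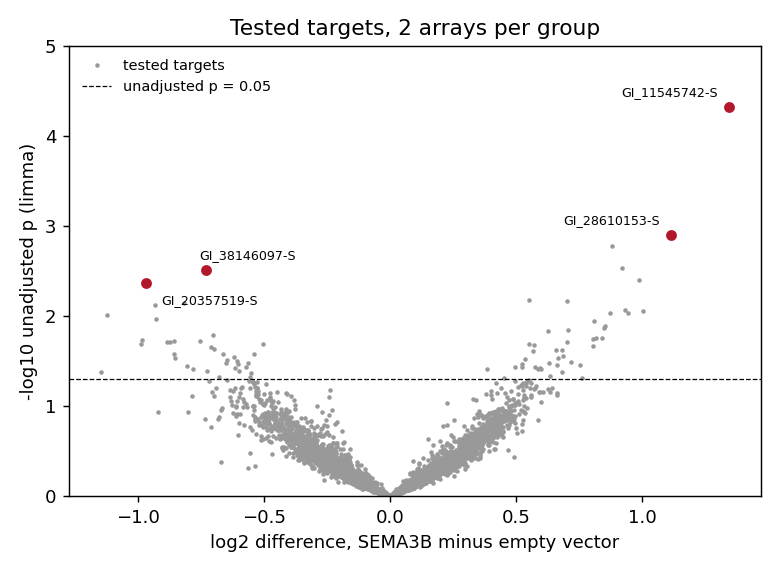
Each point is 1 of 6702 tested targets, with the log2 difference between SEMA3B and empty vector means on the x axis and -log10 of limma's unadjusted p on the y axis; the dashed line marks an unadjusted p of 0.05 and red points are the 4 targets given by identifier. No target passed an adjusted p of 0.05, and GI_11545742-S stood highest with a log2 difference of 1.35.

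The target with the smallest p was GI_11545742-S, at a normalized log2 intensity of 9.41 ± 0.16 (SD, n = 2) in empty vector cells and 10.76 ± 0.10 (SD, n = 2) in SEMA3B cells. The difference of 1.35 (SE 0.23) is 2.54-fold, and its adjusted p from limma was 0.316 (unadjusted 4.7e-05). The second target with higher values, GI_28610153-S, stood at 9.39 ± 0.56 (SD, n = 2) and 10.51 ± 0.11 (SD, n = 2), a difference of 1.12 (SE 0.27) with a limma adjusted p of 1. Its 2 empty vector arrays were themselves apart, at 9.79 and 9.0, against bead errors of 0.078 and 0.071.

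On the lower side, GI_38146097-S was the target with the smallest p. It stood at 11.43 ± 0.19 (SD, n = 2) in empty vector cells and 10.70 ± 0.08 (SD, n = 2) in SEMA3B cells, a difference of -0.73 (SE 0.20) with a limma adjusted p of 1. GI_20357519-S was detected on both empty vector arrays, at 7.50 ± 0.20 (SD, n = 2). On both SEMA3B arrays it narrowly missed the detection cut of 0.01, with a detection p of 0.0105 on each. Its measured mean there was 6.53 ± 0.19 (SD, n = 2). With the main processing the bound on its fold was 1.92, lower in SEMA3B cells. In the fit of the measured values the log2 difference was -0.96 (SE 0.28) with a limma adjusted p of 1, so the fall itself was not established. The size depended on the background correction: the log2 difference was -0.59 with none and -0.64 with normexp and an offset of 50. The other 3 targets were detected on all 4 arrays.

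**Figure D3:**
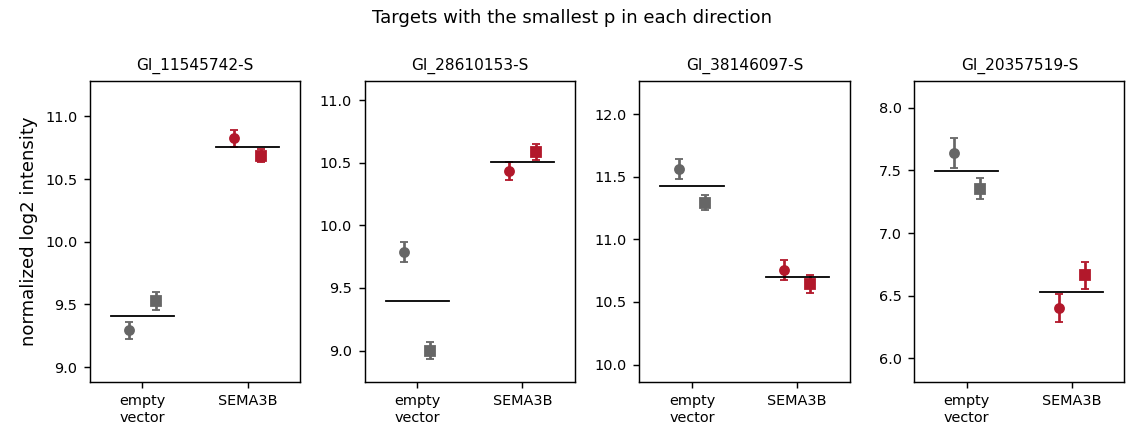
Points are the normalized log2 intensities of the 4 arrays (circle, replicate 1; square, replicate 2) for the 2 targets with the smallest p in each direction, with bars of 1 standard error from the beads of that array and a black line at each group's mean; each y axis spans the same log2 range. The SEMA3B arrays lie on one side of both empty vector arrays in each panel, and the empty vector arrays of GI_28610153-S lie at 9.79 and 9.0.

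The number of targets detected on both arrays of one group and neither of the other was also compared. There were 116 targets detected on both empty vector arrays alone and 13 on both SEMA3B arrays alone. In the remaining split the same numbers were 254, for empty vector replicate 2 with SEMA3B replicate 1, and 23, for empty vector replicate 1 with SEMA3B replicate 2. In the split by replicate number they were 53, for both replicate 2 arrays, and 75, for both replicate 1 arrays. The labelled groups were thus more uneven than one of the other splits, and their 116 was below the 254 of the other. SEMA3B replicate 2 had the fewest detected targets of the 4 arrays.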

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

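No target passed in the main fit, and the count stayed at 0 under 12 of 14 alternatives, with the added array weights and each array left out among the 14. It was 1 with the replicate number as a block (GI_11545742-S, adjusted p 0.0115 from limma), while over the fits with an array left out it ranged from 0 to 4. The labels name nothing that arrays of one number share, and the replicate differences of the 2 groups correlated at -0.01 over all tested targets. The split by replicate number nevertheless called 20 targets, so some targets differed by number in both groups, and 2 pairs of arrays do not settle whether the numbers pair them. The block changed no other count by over 1.5 times. With 0 in the main fit, adding a threshold of at least 2-fold could only give 0. Targets at an unadjusted p below 0.05 numbered 81, rose to 1647 of 47289 with no filter, and ranged from 51 to 401 with an array left out. The share of variation held by the groups was 21.5% and moved beyond its bootstrap SD with no filter alone, to 24.9%. The within-minus-between correlation of -0.0102 was -0.00789 with no background correction, -0.00857 with normexp, -0.00940 with the authors' processed values, -0.00264 with no filter and -0.00952 for targets detected on all 4 arrays. With an array left out it ranged from -0.0201 to 3.2e-04, the latter without SEMA3B replicate 1; the cause was not tested. The 4 targets given by identifier kept their direction under the 4 other ways to obtain log2 values. Their selection fixed it in the other alternatives. The log2 difference of GI_11545742-S ranged from 1.23 to 1.46 (adjusted p 0.0115 to 1), and that of GI_28610153-S from 0.72 to 1.51. That of GI_38146097-S ranged from -0.86 to -0.59, and that of GI_20357519-S from -1.11 to -0.59. With an array left out, the lone array of a group is assumed to vary like the pair of the other. Slide as a block and the gene list alternatives were not run, for want of slides and gene symbols. Signal over background limits what can be tested to the 12.3% to 14.6% of targets detected per array.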

Other observations

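The tests of exchanged labels and extreme targets below were chosen after the results were seen, and those of normalization and of targets of one sequence record before.

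Arrays of one group resembled each other no more than arrays of different groups. Bead errors within arrays accounted for 12.3% of the variance of the replicate differences in empty vector cells and 8.17% in SEMA3B cells. The tables argue against the choice of background correction and normalization as the source. The groups held at most 21.8% of the variation between arrays under the 4 other ways to obtain log2 values, against a chance share of 33.3%. Each of these ways still scaled the arrays to each other, so technical differences between arrays that scaling leaves were not tested. The remaining split sets apart the 2 arrays with the most detected targets, empty vector replicate 2 (6913) and SEMA3B replicate 1 (6557). Other sources stay open. Noise particular to each target could be weighed through 37 pairs of tested targets of the same sequence record, whose replicate differences it would leave uncorrelated. They correlated at 0.415 in empty vector cells (95% bootstrap interval -1.7e-04 to 0.744), with a permutation p of 0.0109 (0.0327 adjusted over the 3 correlations tested). In SEMA3B cells r was 0.2995 (-0.0425 to 0.553), with a permutation p of 0.0745 (0.0745 adjusted). The criterion set beforehand against such noise was an r above 0.3 in both groups, which the SEMA3B arrays narrowly missed. The permutation p was not part of that criterion. These pairs therefore do not decide whether such noise is the source. An exchange of the labels of 2 arrays cannot be told apart from variation between cultures, because the target of SEMA3B is not located. The split by replicate number, which exchanging 2 arrays of different numbers would give, called 20 targets. The remaining split, which exchanging 2 arrays of one number would give, called 0 although it held the most variation, and the labelled groups called 0. Differences between the duplicate cultures stay open as well, untested.

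The largest rise, of GI_11545742-S, may be the most extreme of many targets. Its pairs of arrays lay 1.16 apart on the log2 scale. Other splits of the same arrays gave targets with wider gaps, 1.97 by replicate number and 1.32 in the remaining split. The split by replicate number called 20 targets and both splits held more variation, so neither shows what no effect would give. The wider gaps therefore do not decide it. Which gene GI_11545742-S stands for is not given in the files.

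A difference in RNA, whether between the groups or between the 4 RNA samples, would move both targets of a record together if both report the same transcripts. Whether they do is not given in the sources used here, and the mean log2 levels of the 2 targets correlated at only 0.333. The group differences of the 37 record pairs correlated at Pearson r = 0.328 (Spearman 0.319, 95% bootstrap interval of Pearson's r 0.0142 to 0.612), with a permutation p of 0.0494 and 0.0741 after adjustment over the 3 correlations tested. The r itself was above the 0.3 set beforehand for a difference in RNA, but its interval reaches down to near 0. These pairs therefore do not decide whether the group differences lie in the RNA.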
